A study of Medicago truncatula with 24 samples.

How the data were processed

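Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used on nodules and roots of the legume Medicago truncatula, genotype Jemalong A17, with antibodies against 4 histone H3 marks: H3K9ac, H3K27me3, H3K27me1 and H3K9me2. Per the labels, the series holds 24 samples, of which 20 are immunoprecipitated libraries and 4 are inputs, 1 input per tissue and replicate number. Nodule plants were grown in an aeroponic caisson, were deprived of nitrogen after 7 days, were inoculated with Sinorhizobium meliloti after 4 days of deprivation, and were harvested 10 days after inoculation. Root plants were not deprived of nitrogen and spent 14 days in the caisson. Tissue, nitrogen supply, age and inoculation therefore changed together in every comparison. Samples were grouped by mark and tissue from their titles. Nothing in the labels says whether replicates came from separate cultures, so the agreement between replicates may be technical.

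The deposited files are 14 lists of enriched regions. Per the labels, 1 list was made per mark, tissue and replicate; for H3K9ac, H3K27me1 and H3K9me2 the list of replicate 1 was made from 2 libraries, counted here as 1 replicate. H3K9me2 had 1 list per tissue. The submitters' processing notes name MACS2 2.1.1.20160309 and SICER 1.1. The aligner and the genome build are not given in the sources used here. For H3K9ac, H3K27me1 and H3K9me2 the deposited lists have the MACS2 narrowPeak layout, with a fold enrichment (a ratio to the control) and −log10 p and −log10 q for each peak as the authors' caller gave them. The lowest deposited −log10 q lay between 1.30 and 1.31 in each of these lists. For H3K27me3 the deposited lists hold SICER islands with the count of reads in each island, made per the file names with windows of 200 bp, gaps of 600 bp and a false discovery rate of 0.01. Folds and island reads were used to describe, rank or filter regions within a list. Island reads were also compared between lists, in merged regions. The deposited lists hold no read totals of the libraries, so depth is known only as the reads inside H3K27me3 islands.

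Genes came from the RefSeq gene table of assembly MtrunA17r5.0-ANR. The lists name their sequences with the prefix MtrunA17 but give no version, so the fit was tested before any join. Peaks of H3K9ac covered 16.7% of protein-coding gene bases with the genes in place, 8.62% with the genes moved by 2000 bp to the left and 7.64% with the genes moved by 100000 bp to the left. The overlap was highest without a shift on 8 of 8 chromosomes. Coordinates printed are those of the deposited peaks and islands, counted from 1. Analyses used chromosomes 1 to 8, with 31728 protein-coding genes and 2561 lncRNA genes; regions on other sequences were left out.

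A gene carried H3K9ac where a peak overlapped its body by at least 1 bp, H3K27me3 where islands covered at least 50% of the body, and H3K27me1 where peaks covered at least 10%. Gained in nodules meant carried in both nodule lists and in neither root list, and lost meant the converse. Counts were set beside those of the crossed splits, in which 1 nodule and 1 root list carried the mark and the other 2 did not. With 2 lists against 2, an exact two-sided permutation test cannot go below p = 0.333, so no p was given for list values. The plan written before the data were examined placed H3K9ac calls in a window around the transcript start. The gene table gives no strand, so that window could not be placed, and the whole gene body, set down in the same plan as a second choice, was used. Windows of 500 bp outside to 1000 bp inside either gene end were added after the data were seen. The table gives no product names either, so the 30 word-based gene lists were matched on symbols and synonyms, and 1 of them reached 5 members. Of 41 symbiotic gene names fixed in advance, 14 genes were found by symbol or synonym, with no check of the product. LB1 was taken as the gene with that symbol, which also carries the synonym LB2; another gene, LB6, carries LB1 as a synonym. Exon, intron and repeat shares were not analysed here.

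Fisher's exact test was two-sided, with 95% intervals of the odds ratio from the normal approximation on the log scale after 0.5 was added to each cell, with Benjamini-Hochberg adjustment over 4 tables for pairs of marks and over 8 list-by-set tests. Because neighbouring genes are not independent, the changed sets were also rotated along the gene order 10000 times. On simulated, clustered and unrelated sets, Fisher's test called 34.5% of 200 pairs at p under 0.05 and rotation called 2%, so the rotation p is the one that allows for neighbours. The all-4-list rule, tested on 5000 simulated genes with 5% of marks missed per list, recovered 88% of planted gains with 9 false calls over both directions. Misses were independent and equally frequent in all simulated lists. In the data, the nodule lists of H3K27me3 marked 2777 and 1813 protein-coding genes, with 1611 in both. For H3K9ac the crossed splits of 305, 8, 23 and 7 genes were uneven too. The simulation therefore does not measure false losses of H3K27me3 or H3K27me1, nor false calls of H3K9ac. Reads of H3K27me3 islands were summed per merged region and tested with edgeR 4.0.16 (quasi-likelihood, TMM, R 4.3.3) at an adjusted p under 0.05. On simulated counts for the 3016 regions of that comparison, the fit recovered 11% of the 2-fold and 91% of the 4-fold changes, with 2 false calls, at the common dispersion of the data (0.0915). At a lower dispersion of 0.05 it recovered 50% and 100%, with 5 false calls. Overlaps of marks were compared with 1000 circular shifts along each chromosome in bins of 50 bp. Scripts used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9, and DESeq2 1.42.0 as an alternative test.

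Genes are named by a rule fixed before the data were examined: the symbiotic genes found, and the called genes with the highest rank, the rank being the lower of the percentiles in both lists that carry the mark. The rule asked for an informative product name; here it became a symbol or synonym in the table, and highly ranked genes without one are given by position and identifier. Alternatives were stricter peaks (−log10 q of at least 5), at least 200 bp covered, lists shortened to equal size or equal covered length, coverage of 25% and 75%, other normalisations, leaving out each replicate, and the replicate number as a block. Leaving out a list removes a condition of the all-4-list rule, so gene calls then stay and their counts can only rise.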

Results

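Maps of 4 histone marks were compared between root nodules, formed with the bacterium Sinorhizobium meliloti, and roots of Medicago truncatula that had not been starved of nitrogen. H3K9ac is a mark of active promoters and H3K27me3 is the mark of Polycomb repression. H3K27me1 and H3K9me2 are marks of plant heterochromatin. There were 2 lists per tissue for H3K9ac, H3K27me3 and H3K27me1, and 1 per tissue for H3K9me2, which therefore has no replicate check.

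H3K9ac lists were alike in size in both tissues, whereas the lists of the other marks covered far less of the genome in nodules. H3K9ac covered 21.3 Mb ± 2.77 (SD, n = 2) in nodules and 21.2 Mb ± 1.72 (SD, n = 2) in roots. H3K27me3 islands covered 30.9 Mb ± 12.9 (SD, n = 2) in nodules and 65.5 Mb ± 14.9 (SD, n = 2) in roots. H3K27me1 covered 0.291 Mb ± 0.157 (SD, n = 2) in nodules against 15.0 Mb ± 7.55 (SD, n = 2) in roots, and H3K9me2 covered 0.654 Mb in the nodule list against 11.2 Mb in the root list. The islands of H3K27me3 held 22967933 and 10986479 reads in nodule replicates 1 and 2, and 47870628 and 26837741 in root replicates 1 and 2. Covered length and reads in islands move together, so these totals do not separate depth from the extent of the mark. Of nodule H3K27me1 peaks, 47.2% and 49.6% had −log10 q of at least 5, against 76.9% and 94.3% in roots. Depth or enrichment cannot be told apart from the extent of H3K27me1 and H3K9me2 either.

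**Figure D1:**
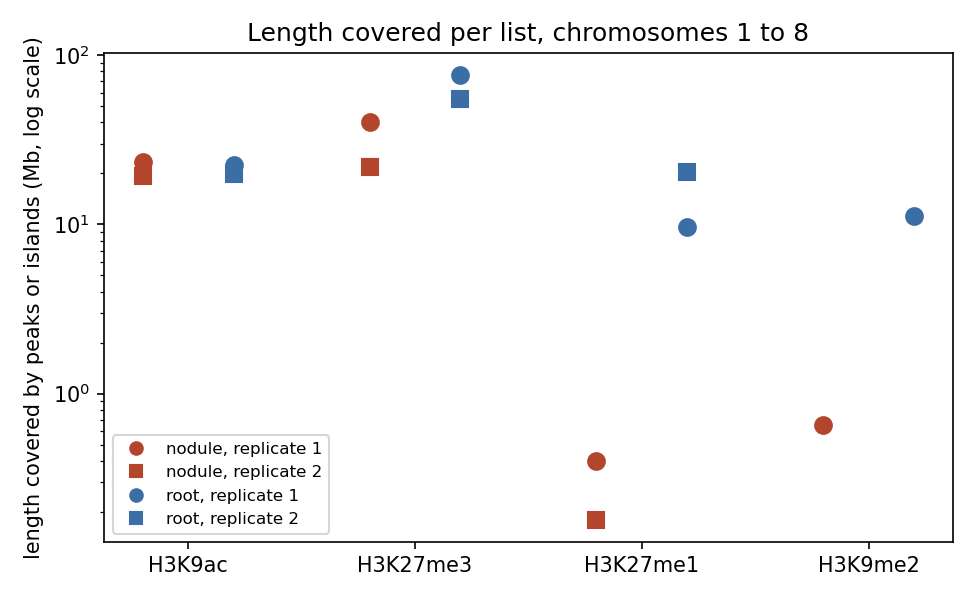
Length covered by peaks or islands on chromosomes 1 to 8 in each of the 14 lists, in Mb on a log axis; colours give the tissue and symbols the replicate, with no error bars. The H3K9ac lists lie close together, while both nodule H3K27me1 lists lie below 0.5 Mb.

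Replicates of H3K9ac shared more covered bases with each other than with the other tissue. The Jaccard index (shared over combined bases) was 0.751 between nodule lists and 0.796 between root lists, against 0.601 to 0.663 between tissues. For H3K27me3 it was 0.564 between root lists but 0.380 between nodule lists. That lay below the 0.436 and 0.498 of nodule replicate 1 with root replicates 1 and 2. The plan was to read a tissue difference only where lists of 1 tissue overlapped more with each other than with the other tissue. H3K27me3 did not meet this rule. Its gains and losses below are differences between the lists, and by the plan they are not read as differences of tissue. H3K27me1 lists of nodules shared almost nothing, with an index of 0.0266 against 0.296 between root lists.

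The gain and loss of H3K9ac in nodules was asked gene by gene. Of 31728 protein-coding genes, 641 gained the mark and 871 lost it, while 15192 carried it in all 4 lists. Among genes with a name, the gained set held LB1, a leghemoglobin gene by its symbol, and the early nodulins ENOD8, ENOD12, ENOD16 and ENOD20. Peaks covered 91.2% ± 12.4 of ENOD16, 88.2% ± 1.02 of ENOD8, 43.6% ± 19.3 of ENOD12, 31.7% ± 8.24 of ENOD20 and 29.5% ± 1.22 of LB1 in nodules (SD, n = 2), and no root peak touched these genes. LB6, which carries LB1 as a synonym in the gene table, had no H3K9ac peak in any list, so the LB1 gain rests on the symbol. The named genes that lost H3K9ac were ERN2, an AP2/ERF transcription factor, LAX4, an auxin influx carrier gene, and the cytochrome P450 gene CYP72A67. Root peaks covered 55.8% ± 7.34 of ERN2, 14.3% ± 4.13 of CYP72A67 and 6.69% ± 1.16 of LAX4 (SD, n = 2).

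Positions of the nodule replicate 1 peaks were chromosome 4, 62672602 to 62673332, at ENOD16, chromosome 1, 10586196 to 10588225, at ENOD8, and chromosome 1, 2110070 to 2110502, at LB1. ENOD12 was overlapped by a peak on chromosome 3, 4695554 to 4696526, and ENOD20 by one on chromosome 4, 62678985 to 62679543. The ERN2 peak of root replicate 1 lay on chromosome 6, 10504381 to 10505133. The highest ranked gained gene, LOC11432827, lay under a peak on chromosome 7, 54466413 to 54470925, with the authors' fold enrichment of 3.83 in nodule replicate 1. For the lost set it was LOC25497835, on chromosome 7, 10621660 to 10623568, with 3.77 in root replicate 1. Crossed splits gave 305 genes with H3K9ac in both lists of replicate 1 alone, 8 in both of replicate 2 alone, and 23 and 7 in the diagonal splits. Gained and lost genes thus exceeded each crossed split. Leaving out a list drops a condition, so counts can only rise: without nodule replicate 2 the gained genes numbered 1009, and the lost genes numbered 1933 without nodule replicate 1 and 1583 without root replicate 2. Calls at ENOD12, LB1, LAX4 and CYP72A67 were not made with peaks of −log10 q of at least 5. That at ENOD12 was also not made with at least 200 bp covered, nor those at LAX4 and CYP72A67 with lists of equal size.

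**Figure D2:**
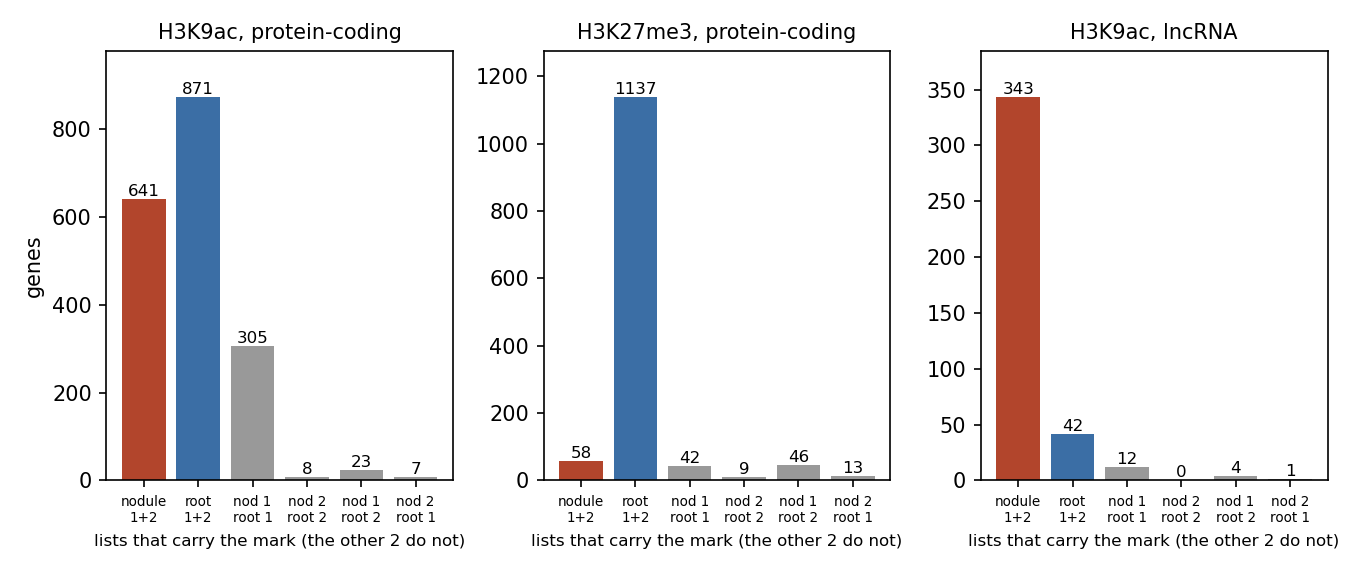
Number of genes that carry the mark in exactly the 2 lists named on the horizontal axis and in neither of the others, for H3K9ac at protein-coding genes, H3K27me3 at protein-coding genes and H3K9ac at lncRNA genes; bars are counts without error. The first and second bars are the genes called gained and lost in nodules. The grey bars are the crossed splits, of which the largest for H3K9ac at protein-coding genes holds 305 genes.

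Other symbiotic genes carried H3K9ac in all 4 lists. This held for 9 of the 14 found: NSP1, NSP2, ERN1, IPD3, DMI3, Vpy, SUNN, NOOT1 and CCS52A. Nodule peaks covered 93.1% ± 1.82 of NSP1, a GRAS transcription factor of nodulation signalling, and root peaks 55.7% ± 0.910 (SD, n = 2 each). For Vpy, an ankyrin-repeat protein of infection, the values were 86.1% ± 2.02 and 44.5% ± 0.759, and for IPD3, a transcription factor of the common symbiosis pathway, 67.2% ± 2.19 and 32.6% ± 3.67. NSP2 had 58.2% ± 20.5 in nodules and 83.6% ± 0.996 in roots. NFP, a Nod factor receptor, had a peak in nodule replicate 1 alone, and ENOD11 had none in any list.

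H3K27me3 was called lost from 1137 protein-coding genes in nodules and gained at 58, but the balance depended on the lengths of the lists. With each list shortened to the covered length of the shortest, keeping the islands with most reads per kb, 30 genes were lost and 214 gained. Named genes that lost the mark were NOOT1 and NOOT2, co-transcriptional regulators of nodule identity, SUNN, a receptor kinase that limits nodule number, ENOD12, ENOD16 and RAM2, a gene of arbuscular mycorrhiza. Root islands covered 100% of ENOD12, 92.3% of ENOD16, 89.3% ± 4.09 of NOOT1, 72.9% ± 3.90 of NOOT2 and 54.6% ± 3.67 of SUNN (SD, n = 2), and no nodule island touched them. RAM2 kept islands over 35.6% ± 4.92 in nodules, against 59.1% ± 8.66 in roots (SD, n = 2), and its loss was called at coverage of 50% but not at 25% or 75%, nor when no island was allowed in nodules. None of the losses at these 6 genes was called in the lists of equal length, where RAM2 had more coverage in nodules, and those at NOOT2 and SUNN were not called at 75%. CYP81E7, a cytochrome P450 gene, gained the mark, at 68.2% ± 15.2 in nodules (SD, n = 2) and no island in roots, and this gain was not called in the lists of equal length or at 75%.

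Root islands at ENOD12 ran from 4665801 to 4727400 on chromosome 3, at ENOD16 from 62672601 to 62676200 on chromosome 4, and at NOOT1 from 42203801 to 42207000 on chromosome 7, in root replicate 1. The nodule replicate 1 island at CYP81E7 ran from 46856401 to 46858600 on chromosome 4. Highest in rank among lost genes was LOC120576832, in an island on chromosome 7, 6582001 to 6650200, with 1155 reads per kb in root replicate 1. ENOD11 was covered to 94.8% in nodule replicate 1 and to 0 in replicate 2, with 100% in both root lists. Protease inhibitor genes KPI104 and KPI111 were covered in all 4 lists. Crossed splits gave 42, 9, 46 and 13 genes, so the 58 gained genes stood little above the largest of them. Losses numbered 2137 without nodule replicate 1 and 1914 without root replicate 1, and gains numbered 204 without nodule replicate 1 and 136 without nodule replicate 2.

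Root islands over genes that lost H3K27me3 were weaker. Genes covered in both root lists and either lost or kept in both nodule lists were ordered by their root island reads per kb into 5 groups of near-equal size, a split chosen after the losses were seen. In the group with the fewest reads, at a median of 306 reads per kb, 85.6% had lost the mark. In the group with the most, at 594 reads per kb, 16.5% had.

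**Figure D3:**
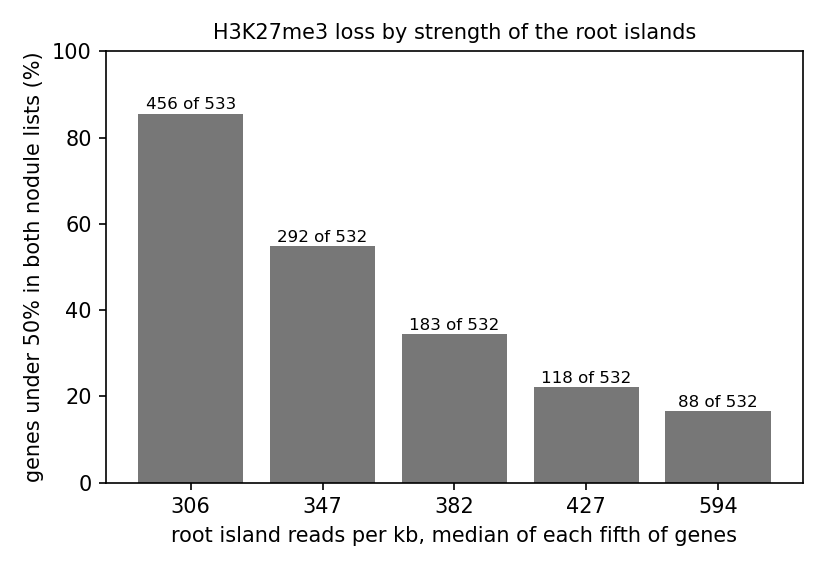
Percentage of protein-coding genes with H3K27me3 in both root lists that were called lost in nodules, for 5 groups of genes ordered by root island reads per kb (horizontal axis, median of each group); bars are shares and the labels give the counts. The share falls from 85.6% to 16.5%.

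Island reads were compared in 3016 merged regions with an H3K27me3 island in each of the 4 lists. Nodules had fewer reads in 31 regions and more in 5 (edgeR quasi-likelihood test, adjusted p under the threshold). A region on chromosome 3, 4788001 to 4809600, was lower by a log2 ratio of -3.66 (adjusted p = 0.0458), with 434 and 422 reads in nodules and 8941 and 7911 in roots. On chromosome 7, 16688001 to 16692200 was higher, at a log2 ratio of 2.32 (adjusted p = 0.0458). Reads were summed over islands called in each list, and the covered length moved with them: its median log2 ratio was -2.97 in the lower and 1.51 in the higher regions. In the chromosome 3 region, reads per kb of island were 362 and 422 in nodules and 430 and 373 in roots. DESeq2's Wald test called 1073 regions, 595 higher and 478 lower, so the split between directions depended on the test. Leaving out any 1 list raised the number of called regions. A tissue then has 1 list and the spread comes from the other tissue alone, so those counts are not read.

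Genes that gained H3K9ac and lost H3K27me3 were more frequent than independent sets would give. There were 73 such genes, ENOD12 and ENOD16 among them, against 23.0 for independent sets (Fisher's exact test, odds ratio 3.63, 95% interval 2.84 to 4.69, adjusted p = 1.26e-17). A permutation test that rotated the set along the gene order, added after the data were seen, gave p = 1.00e-04. This is the smallest that 10000 rotations can give. Neither test allows for where the marks lay in roots. Only genes without root H3K9ac can gain it, and only genes with root H3K27me3 can lose that mark. In roots these marks overlapped at 0.227 to 0.413 times the mean of shifted positions. Part of the excess may therefore precede any change, and it was not separated. Both nodule lists covered 75.9% ± 3.88 of NOOT2 and 66.2% ± 4.99 of NOOT1 with H3K9ac, against 14.0% ± 0.624 and 16.1% ± 2.66 in roots (SD, n = 2), although these genes had the mark in all lists. SUNN, which also lost H3K27me3, went the other way, with H3K9ac over 35.5% ± 5.73 in nodules and 47.0% ± 1.75 in roots (SD, n = 2). RAM2 had no H3K9ac peak in any list. The converse, H3K9ac lost with H3K27me3 gained, held 2 genes against 1.59 (adjusted p = 0.674, Fisher's exact test). Without H3K27me3 nodule replicate 2 it held 9 against 3.73 (adjusted p = 0.0259, Fisher's exact test). Same-direction tables held 0 genes gained in both marks and 37 lost in both, against 31.2 (adjusted p = 0.536, Fisher's exact test). Both tables passed the threshold with some lists left out: 11 genes gained both marks without H3K27me3 nodule replicate 1, against 4.12 (adjusted p = 0.00614, Fisher's exact test), and 86 lost both without H3K9ac root replicate 2, against 56.7 (adjusted p = 2.55e-04, Fisher's exact test). Without H3K27me3 root replicate 1, 74 lost both, against 52.5 (adjusted p = 0.00603, Fisher's exact test), and for nodule replicate 1 against root replicate 2 of H3K27me3, 76 did, against 53.7 (adjusted p = 0.00347, Fisher's exact test). No rotation was run for the tables with lists left out, and Fisher's test does not allow for neighbouring genes. The marks share input libraries, and part of any overlap may come from them. In the lists of equal covered length 0 of the 30 lost genes had gained H3K9ac, against 0.606 expected, while 15 of the 214 gained genes had lost H3K9ac, against 5.88 expected (adjusted p = 0.00361, Fisher's exact test).

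**Figure D4:**
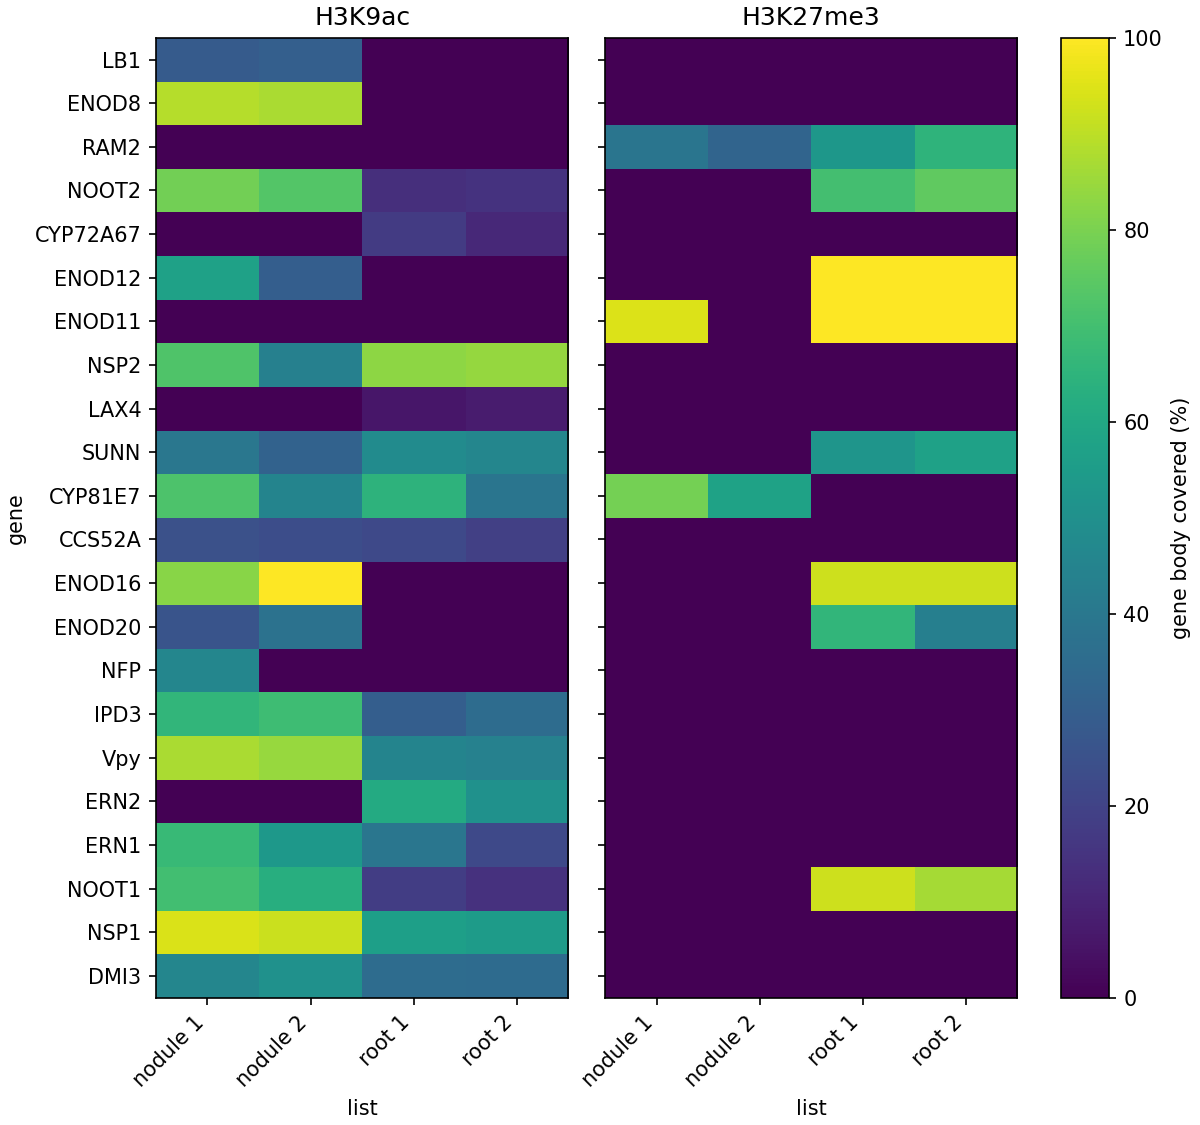
Percentage of the gene body covered by H3K9ac peaks (left) and H3K27me3 islands (right) in each list, for the symbiotic genes found and the named genes called in either mark; each cell is 1 list. ENOD12 and ENOD16 are covered by H3K9ac in nodules and by H3K27me3 in roots.

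Symbiotic genes and nodulins were over-represented in the changed sets when set against all protein-coding genes. Of 14 symbiotic genes, 3 gained H3K9ac (LB1, ENOD12 and ENOD20; odds ratio 13.3, adjusted p = 0.0101, Fisher's exact test; adjusted rotation p = 0.0148) and 3 lost H3K27me3 (ENOD12, SUNN and NOOT1; odds ratio 7.35, adjusted p = 0.0331, Fisher's exact test; adjusted rotation p = 0.032). Of 6 nodulins, named from nodule-induced transcripts, 4 gained H3K9ac (ENOD8, ENOD12, ENOD16 and ENOD20; odds ratio 97.6, adjusted p = 1.92e-05, Fisher's exact test; adjusted rotation p = 8.00e-04). ENOD12 and ENOD16 lost H3K27me3 (odds ratio 13.5, adjusted p = 0.0350, Fisher's exact test; adjusted rotation p = 0.0458). The lists share ENOD11, ENOD12 and ENOD20, and no member of either lost H3K9ac or gained H3K27me3. ERN2, which lost H3K9ac, was in neither list. The H3K9ac gain of symbiotic genes rested on LB1 and ENOD12: with −log10 q of at least 5 it held 1 of 14 (adjusted p = 0.419, Fisher's exact test) and with at least 200 bp covered 2 of 14 (adjusted p = 0.0626, Fisher's exact test). The H3K27me3 loss of symbiotic genes was not called at 75% coverage, with 2 of 14 (adjusted p = 0.151, Fisher's exact test). Neither test of H3K27me3 loss was called in the lists of equal length or without H3K27me3 root replicate 1, where both had an adjusted p = 0.0968 (Fisher's exact test). The background of each test was the 31728 protein-coding genes. Only the 77 of them with a symbol or synonym could enter a list. The tests therefore also compare named with unnamed genes, and a background of named genes was not tested.

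H3K27me1 and H3K9me2 were nearly confined to the root lists. By gene, 416 protein-coding genes lost H3K27me1 and 8 gained it, with 856 and 554 genes marked in root replicates 1 and 2 against 52 and 36 in nodules. Crossed splits gave 18, 1, 0 and 20 genes, so the gained genes were fewer than in 2 of these splits. With the lists shortened to the number of peaks in the smallest, 0 genes were called lost and 3 gained. Gains numbered 23 without nodule replicate 2, and losses 804 without root replicate 2. Peaks of H3K9me2 numbered 1891 in the nodule list and 23842 in the root list, and 43.1% of the nodule bases lay in root peaks.

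Positions of the marks differed in kind. Protein-coding genes, 30.5% of the sequence spanned, held 78.0% to 80.2% of H3K9ac bases, 17.4% to 24.6% of H3K27me3 bases and 7.83% to 15.5% of H3K27me1 bases. In roots, H3K9ac of replicate 1 overlapped H3K9me2 at 0.0129 times the mean of 1000 shifted positions. In nodules the H3K9ac lists of replicates 1 and 2 overlapped the far smaller H3K9me2 list at 1.51 and 2.12 times that mean, more than in any shift. Root H3K27me1 peaks lay largely within H3K27me3 islands of root replicate 1, with 64.9% and 87.7% of the bases of replicates 1 and 2, but less so within those of root replicate 2, with 22.4% and 30.5%. In total 19 of 36 pairs of lists of different marks within a tissue overlapped more than any shift, and 16 overlapped less than any.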

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

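No group held enough lists to test for a list far from the others. Of the tests below, that with lists of equal covered length was chosen before its result was seen; the tests of island strength and of the H3K27me1 lists were chosen after related values had been seen. Regions outside chromosomes 1 to 8, in sequence that no comparison used, were found in the lists: 14 peaks on the chloroplast sequence, each from H3K27me1 of root replicate 2, and 3534 peaks and islands on unplaced scaffolds over the 14 lists. No explanation was tested for either.

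H3K27me3 was called lost from 1137 genes and gained at 58. With lists of equal covered length the ratio of lost to gained genes was 0.140, and the share of lost genes was 5.17 times higher in the group with the weakest root islands than in that with the strongest, which is consistent with fewer or weaker called islands in nodules as a source of the imbalance. Equal lengths would also remove a loss of the mark spread over the genome, so tissue, nitrogen supply and age stay open, untested. Within groups of like root island strength, H3K9ac gain went with H3K27me3 loss at a common odds ratio of 18.2 (95% interval 7.5 to 44.3). Weaker islands alone predicted an interval that includes 1. The ratio rested on the 3 weakest groups, where 26, 21 and 21 lost genes had gained H3K9ac, against 0, 0 and 1 kept genes. In the other groups 2 of 118 and 3 of 88 lost genes had, against 2 and 6 of the more numerous kept genes. Kept genes carry nodule H3K27me3, which overlapped nodule H3K9ac at 0.264 to 0.583 times shifted positions. A ratio above 1 may follow from that choice, so the test does not settle the cause. In the lists of equal length 0 of the 30 lost genes had gained H3K9ac, with 0.606 expected, which is too few to speak for either side.

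Of 1088 nodule replicate 1 H3K27me1 peaks, 72.3% overlapped the nodule H3K9me2 list and 5.70% overlapped replicate 2 of the same mark and tissue. Those lists differ in size, with 1891 peaks over 0.654 Mb and 562 over 0.180 Mb, so the shares are not on an equal footing. Nodule replicate 2 H3K27me1 also overlapped H3K9me2, at 43.5 times the mean of shifted positions, against 465 times for replicate 1. An input library shared by the lists of replicate 1 cannot be told apart from other sources. That reading holds only by a criterion widened after its first result. The first form used the nodule replicate 1 H3K27me1 list alone. Its overlap with nodule H3K9ac, as a ratio to shifted positions, was 0.670 times as high for replicate 1 as for replicate 2 (2.39 and 3.56). By that form this spoke against a shared input. The test was then widened to both nodule H3K27me1 lists, and replicate 2 of H3K27me1 also overlapped H3K9ac of replicate 2 more (0.160 and 2.23), so the lists went opposite ways. Regions that carry both marks in roots too are argued against as the source of most of it, since 27.3% of the shared peaks overlapped the root H3K9me2 list. Tissue, nitrogen supply and age were not tested.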

How the results depend on the processing

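The windows at the gene ends, nodule replicate 1 against root replicate 2, and the rotations of opposite changes and of nodule H3K27me1 or H3K9me2 peaks were added after the data were seen. H3K9ac genes numbered 528 to 767 gained and 868 to 985 lost with stricter peaks, 200 bp of overlap, equal list sizes and windows at the gene ends; of the 641 and 871 genes reported, 394 and 521 were also called with −log10 q of at least 5. Leaving out each list gave 669 to 1009 gained (highest without nodule replicate 2) and 894 to 1933 lost genes (1933 without nodule replicate 1, 1583 without root replicate 2). H3K27me3 losses became 30 and gains 214 with lists of equal covered length, and 1957 and 189 for nodule replicate 1 against root replicate 2. Leaving out each list gave 1171 to 2137 losses (2137 without nodule replicate 1, 1914 without root replicate 1) and 69 to 204 gains (204 without nodule replicate 1, 136 without nodule replicate 2). H3K27me1 gains became 0 at −log10 q of at least 5 and 3 with equal list sizes, where losses became 0; leaving out each list gave 8 to 23 gains (23 without nodule replicate 2) and 419 to 804 losses (804 without root replicate 2). By construction, equal sizes and lengths leave fewer regions, and leaving out lists drops conditions, so calls stay and counts only rise; otherwise the cause was not tested.

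The odds ratio of H3K9ac gain with H3K27me3 loss was 2.07 to 4.79 under the other alternatives and 0 with lists of equal covered length, where 30 lost genes were left and 0.606 was expected; the cause was not tested. The other tables passed the threshold under some alternatives by Fisher's exact test, which does not allow for neighbouring genes. Rotation was not run for these alternatives. Both marks were lost at 86 genes without H3K9ac root replicate 2 (56.7 expected, adjusted p = 2.55e-04), 74 without H3K27me3 root replicate 1 (52.5 expected, adjusted p = 0.00603) and 76 for nodule replicate 1 against root replicate 2 (53.7 expected, adjusted p = 0.00347). Both were gained at 11 without H3K27me3 nodule replicate 1 (4.12 expected, adjusted p = 0.00614). H3K9ac loss with H3K27me3 gain held 9 genes without H3K27me3 nodule replicate 2 (3.73 expected, adjusted p = 0.0259), 14 for nodule replicate 1 against root replicate 2 (5.19 expected, adjusted p = 0.00155) and 15 with lists of equal covered length (5.88 expected, adjusted p = 0.00361). Of 8 gene list tests, 4 were called as reported, 3 with −log10 q of at least 5, with 200 bp of overlap (the H3K9ac gain of symbiotic genes ended in both) and at 75% coverage (their H3K27me3 loss ended), and 2 with lists of equal covered length, without H3K27me3 root replicate 1, and for nodule replicate 1 against root replicate 2; leaving out each list gave 2 to 4. Changed H3K27me3 regions numbered 36 with edgeR (800 at an unadjusted p under 0.05), 1073 with DESeq2, and 61 to 1544 when leaving out each list, 450 without nodule replicate 2 and 67 without root replicate 1; the cause was not tested. In 3016 H3K27me3 regions, same-numbered lists deviated with a correlation of 0.0585, so no pairing was used. For H3K9ac, 305 genes had the mark in both lists of replicate 1 alone and 8 in both of replicate 2 alone, against 23 and 7 in the diagonal splits. A tie by number was thus not seen for replicate 2. The replicate 1 lists came from 2 libraries each and covered 23.2 and 22.4 Mb, against 19.3 and 20.0 Mb in replicate 2. Longer lists and a tie by number cannot be told apart there, nor at rRNA and snoRNA genes of H3K27me3. The replicate block gave 86 regions, and the gene counts of 641, 871, 1137 and 58 as reported, by construction of the rule. Under rules that can end a call, calls at named genes held in 40 of 60 alternatives and ended in 19; RAM2 reversed, with H3K27me3 over 2.97 percentage points more in nodules with lists of equal covered length. The promoter window around the transcript start was not run, for want of strand.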

Other observations

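The tests of lncRNA and snoRNA genes and of nodule H3K27me1 or H3K9me2 peaks below, and the runs of genes, were chosen after the patterns had been seen. Genes for long non-coding RNAs (lncRNAs) gained H3K9ac in nodules far more often than they lost it, unlike protein-coding genes. Of 2561 lncRNA genes 343 gained the mark (13.4%) and 42 lost it (1.64%), against 2.02% and 2.75% of protein-coding genes. Among changed genes, gain against loss had an odds ratio of 11.1 for lncRNA against protein-coding genes (95% interval 7.86 to 15.3). Rotation along the order of the changed genes, a permutation test that keeps neighbours together, gave p = 5.27e-04, the smallest that its 1897 positions can give. Over the alternative rules, 254 to 413 lncRNA genes gained and 38 to 80 lost the mark, with 80 lost both without nodule replicate 1 and without root replicate 2. The crossed splits gave 12, 0, 4 and 1 lncRNA genes. H3K27me3 was called lost from 182 lncRNA genes and gained at 10, but lost from 2 and gained at 24 in lists of equal covered length. Leaving out each list gave 189 to 265 lost and 10 to 43 gained, with 43 gained without nodule replicate 1 and 17 without nodule replicate 2. Of the 182, 56 had gained H3K9ac, against 24.4 for independent sets (rotation along the order of the lncRNA genes, permutation p = 3.90e-04, the smallest that 2561 positions can give), and in lists of equal covered length 0 of the 2 had. This rotation does not allow for where the marks lay in roots either. Among small RNA genes, 197 of 971 snoRNA genes (20.3%) had H3K27me1 in both root lists and in no nodule list, and 1 had with lists of equal size. Equal size cut the root lists from 31435 and 40395 peaks to 570, which removes most root calls in any case. The fall therefore cannot show whether the far shorter nodule lists made the count. Leaving out each list gave 197 to 355, the most without root replicate 1.

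Some changed genes lay side by side, where 1 peak or island can reach more than 1 gene. On chromosome 2, from 50727381 to 50756331, 5 neighbouring genes gained H3K9ac, with 33.4% and 45.3% of the interval covered in nodules and none in roots. Root H3K27me3 covered 60.9% and 61.6% of it and nodule H3K27me3 none. A longer run of 8 genes, on chromosome 6 from 1096929 to 1132892, had H3K9ac over 35.6% and 57.8% in nodules, with H3K27me3 over 52.5% in nodule replicate 2 and 1.67% in replicate 1. Another run, on chromosome 7 from 40933676 to 40954951, had nodule peaks of each mark: 14.5% and 60.3% was covered by H3K9ac, 16.2% and 7.53% by H3K27me1, 11.8% by H3K9me2, and 99.4% by H3K27me3 in nodule replicate 2, while nodule replicate 1 had no H3K27me3 there. Of the 58 genes that gained H3K27me3, 10 carried a nodule H3K27me1 or H3K9me2 peak (17.2%), against 0.935% of other genes (Fisher's exact test, odds ratio 22.1, adjusted p = 8.34e-10). Nodule H3K27me3 overlapped nodule H3K27me1 at 2.65 to 13.9 times and H3K9me2 at 3.89 and 8.10 times the mean of shifted positions, so part of this excess belongs to nodule H3K27me3 in general. Among genes with H3K27me3 in both nodule lists, 2.25% of the 1553 that had not gained it carried such a peak (Fisher's exact test, odds ratio 9.04, 95% interval 4.39 to 19.5). Rotation within these genes gave a permutation p = 6.21e-04, the smallest that 1611 positions can give. Of these 58 genes, 4 lay under 1 island per nodule list on chromosome 2, from 19282601 to 19308400, with H3K9me2 over 19.7% in nodules and 8.47% in roots. Runs of 3 genes on chromosome 7, 25073601 to 25102400, and 2 on chromosome 3, 22412001 to 22418400, had no nodule H3K27me1 or H3K9me2. Root H3K9me2 covered 7.37% and 40.9% of these, and root replicate 1 H3K27me1 13.3% and 34.3%, with none in root replicate 2. Root peaks at the 58 genes were not tested. For nodule peaks, the 3 other changed sets gave an adjusted p of 0.291 by Fisher's exact test and of 0.207 to 0.919 by rotation, a permutation test.

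The gain of H3K9ac at lncRNA genes was weighed against technical explanations. Peaks of neighbouring protein-coding genes are argued against as its source: among 1940 lncRNA genes with no protein-coding gene within 1 kb, 300 gained and 30 lost the mark, a ratio of 10. Short length is argued against too, with a common odds ratio of 9.85 (95% interval 6.97 to 13.9) within 5 length classes. Gene models built from nodule transcripts may favour lncRNAs active in nodules. The ratio of 8.17 gained to lost lncRNA genes cannot be told apart from such a choice, because the gene table records no tissue for its models, and tissue, nitrogen supply and age stay open, untested.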
